A study of Homo sapiens with 9 samples.

How the data were processed

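RNA sequencing of THP-1 cells gave 9 libraries in 3 groups of 3, untreated, ATRA at 8 µM and PMA at 50 ng/mL, per the labels. The duration of treatment, the vehicle and whether the replicates were separate cultures are not stated in the labels. The labels' extraction protocol speaks of retinas, which does not match a cell line, so it was not relied on. FPKM per transcript (fragments scaled by transcript length and by the mapped fragments of the library) were deposited by the authors, who list HISAT2 2.0.5, StringTie, Cuffdiff and edgeR with the hg38 and GRCh38 builds, per the submitters' processing notes. Those notes do not state which tool made the values, nor whether strand was used. No further scaling between libraries is stated there, and none was applied before the fit.

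The table was compared with GENCODE 29 on GRCh38 by transcript ID. Of its 108003 transcripts, 103347 have Ensembl IDs and 4656 are assembled, and 63220 were above 0 in at least 1 library. Of the Ensembl transcripts 84072 were in GENCODE 29, 81170 of them (96.5%) with the same coordinates. The table holds 28056 retained-intron, 28443 processed-transcript, 14344 lincRNA and 11418 antisense models but 123 protein-coding and 27 nonsense-mediated decay models, where GENCODE 29 has 83101 and 15283 of these 2 classes. It is therefore a part of each library, and the FPKM sums are not depths. Depth was estimated per library from the spacing of low FPKM values of single-exon transcripts, searched over a fixed range of spacings. Between 22.2% and 26.8% of values lay on the steps. The estimates were 28.5 M, 25.7 M and 25.4 M fragments for untreated, 27.8 M, 32.4 M and 28.9 M for ATRA and 28.4 M, 27.7 M and 25.1 M for PMA. Of the table's 31845 gene names 16835 are lncRNA genes, 13788 protein-coding genes and 1214 pseudogenes. The class came from GENCODE 29 for 29874 names and from the form of the name for 1963. The estimates for isoforms can jump between replicates, and 1114 transcripts hold the gene of a small RNA in an exon.

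For each gene the FPKM of its transcripts were summed by gene name, 16 names being shared by 2 gene IDs, and transcripts without a gene name stayed out of the gene level. Genes and transcripts with a mean FPKM of at least 0.5 over the 9 libraries were tested on log2 of FPKM plus 0.5. The fit was limma 3.58.1 in R 4.3.3 with an intensity trend, over all 9 libraries and 3 groups, two-sided, with Benjamini-Hochberg adjustment within each comparison, and a gene passed at an adjusted p under 0.05. Every adjusted p of a gene or transcript is from this limma fit unless said otherwise. The comparisons were ATRA against untreated, PMA against untreated and PMA against ATRA. Values are means ± SD of 3 libraries.

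Gene lists of retinoid response, AP-1 and early response, macrophage markers, granule genes, NADPH oxidase, adhesion, cytokines, NF-kappaB, lysosome and proteases, cell cycle, p53 targets, MYC and ribosome biogenesis, MLL-fusion targets, myeloid transcription factors, interferon response, lipid loading and LXR, cholesterol synthesis, glycolysis and hypoxia, lncRNAs, and stress, with smaller lists of MHC class II, mitochondrial genes, cell type markers and the study's genes, were written before the data were examined. Of their 622 genes 461 were in the table. The 20 lists with at least 3 tested members were tested with camera of limma at a preset correlation of 0.01, adjusted over the 60 tests, and again with a correlation estimated from the data. Members were also adjusted over their list alone.

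Named genes followed a rule written before the data were examined. It took the 10 largest rises and 10 largest falls per comparison among genes that passed, had a mean of at least 5 FPKM and whose groups did not overlap, and up to 4 members per list with the smallest adjusted p. It also took the study's genes, the 5 largest rises and 5 largest falls among lncRNA genes changed the same way by both inducers, ranked by the smaller of the 2 changes, and up to 5 genes per inducer with transcripts moving in opposite directions at a mean of at least 1 FPKM. The number of genes shared by both inducers was set beside that expected from independent draws. It was also set beside 100 simulated pairs of unchanged groups with a shared untreated group.

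Simulated data with 200 changed genes among 8500 gave the sensitivity of the gene fit at that number of changes. Sensitivity depends on this number, so the values do not carry over to PMA, which had 2108 calls in the data. For ATRA against untreated the fit recovered 17% of 2-fold and 76% of 4-fold changes with 8.82% false among 102 calls. For PMA against untreated it recovered 22% and 73% with 4.04% false among 99 calls. For 200 changed among 15235 transcripts it recovered 3% and 47% for ATRA (5.66% false among 53 calls) and 6% and 54% for PMA (1.64% false among 61 calls). Of 100 unchanged lists, 2 and 3 had a camera p under 0.05 in the same 2 comparisons. The simulated genes were drawn independently of each other, so this rate does not carry over to lists with correlated members. In the data the estimated correlation was as high as 0.216, for the MLL-fusion target list.

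Alternatives were a pseudocount of 1 or 0.1, no filter on low values, a mean of at least 2 FPKM, scaling to the same sum, median-of-ratios scaling, quantile normalization, eBayes without the trend, the replicate number as a block, a fit of only the 2 groups compared, and each library left out in turn. Leaving out transcripts that hold a small RNA gene, and applying the alternatives to the counts of lncRNA genes, the share of rising genes and the isoform switches, was chosen after the data had been seen. Correlations between neighbouring genes used 2000 bootstrap draws and 1e+05 permutations, and the isoform comparison used 10000 sign flips. Figures and tables were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. Transcripts of loci without a gene name were tested at the transcript level only. Single results on 2 items are not reported here.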

Results

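RNA was sequenced from THP-1, a human acute monocytic leukemia cell line, in 9 libraries. There were 3 libraries of untreated cells, 3 of cells given 8 µM all-trans retinoic acid (ATRA, the ligand of the retinoic acid receptors) and 3 of cells given 50 ng/mL phorbol 12-myristate 13-acetate (PMA, an activator of protein kinase C). Both compounds make these cells differentiate, and the stated question was which long noncoding RNAs (lncRNAs) and messenger RNAs change with both. The table that was analysed lists FPKM for 108003 transcripts, and nearly all of them are noncoding models: it holds 28056 of the 28087 retained-intron models of GENCODE 29 but 123 of its 83101 protein-coding models. A protein-coding gene is therefore named here for the sum of the noncoding transcripts listed under it, such as a retained-intron isoform, and messenger RNA was not analysed here. CDC5L, named in the title of the series, had no transcript in the table. Depth, estimated from the spacing of low FPKM values, lay between 25.1 M and 32.4 M fragments per library, and the listed FPKM summed to 47900.9 to 53852.4 per library. Untreated cells had 6196 ± 232 genes at 1 FPKM or more (SD, n = 3), ATRA cells 6085 ± 35.8 and PMA cells 5620 ± 43.7. After the filter on low values, 8500 genes and 15235 transcripts were tested. The first principal component of the 8500 genes held 48.7% of the variance and parted the PMA libraries from the other 6. Untreated replicate 3 stood apart on the second component, at 48.8 against 4.7 and 12.1 for the other untreated libraries, and its mean correlation with them was 0.840 against 0.866 and 0.865 for the other 2.

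The first comparison asked what ATRA changed in these cells. AC254633.1, a lincRNA, rose from 0.110 ± 0.118 to 9.18 ± 1.21 FPKM (SD, n = 3 in each group), and DHRS3, a retinal-reducing enzyme, rose from 0.204 ± 0.146 to 10.5 ± 1.34 FPKM. CD38, a surface enzyme that retinoic acid is known to induce in myeloid cells, rose from 3.11 ± 0.460 to 21.6 ± 0.639 FPKM. CHI3L1, a secreted chitinase-like protein of macrophages, rose from 144 ± 43.8 to 1215 ± 54.2 FPKM, and ACSL1, which activates long-chain fatty acids, rose from 1.09 ± 1.26 to 22.9 ± 10.4 FPKM. MYO1G, a myosin of blood cells, fell from 34.3 ± 2.33 to 9.56 ± 0.880 FPKM, and ARMH1 fell from 45.0 ± 1.88 to 12.3 ± 3.10 FPKM. In the limma fit, 57 genes rose and 33 fell of the 8500 tested at an adjusted p under 0.05, against 1114 genes at an unadjusted p under 0.05. Among them were 26 of the 1418 lncRNA genes, of which 15 rose, and 63 of the 6913 protein-coding genes, of which 41 rose. The median log2 change of all genes was 0.00, and in 19.7% of genes the 3 ATRA values did not overlap the 3 untreated values, against 10% given by chance.

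The log2 changes, on the scale of FPKM plus 0.5, were 4.0 for AC254633.1 (SE 0.224, adjusted p = 4.21e-05), 3.98 for DHRS3 (SE 0.231, adjusted p = 4.21e-05) and 2.62 for CD38 (SE 0.202, adjusted p = 2.8e-04). They were 3.12 for CHI3L1 (adjusted p = 0.00158), 4.06 for ACSL1 (adjusted p = 0.0076), -1.79 for MYO1G (adjusted p = 0.00888) and -1.85 for ARMH1 (adjusted p = 0.00355). AC254633.1 (ENSG00000272482) lies on chromosome 1 at 12618900 to 12619244 of GRCh38, on the minus strand, 1169 bases from DHRS3 on the same strand. The other genes with large rises were RCAN1, an inhibitor of calcineurin, at 0.0492 and 16.1 FPKM, the RNA helicase DDX56 at 1.72 and 17.5, the pseudogene NCF1B at 2.63 and 20.6, the stress-induced NDRG1 at 4.85 and 32.1, and CTSL, the lysosomal protease cathepsin L, at 4.08 and 23.0. The NCF1B value is uncertain, since its reads can be shared with NCF1, a near-identical copy. Large falls were also seen for the galectin LGALS3, from 3.42 to 0.513 FPKM, the calpain CAPN2, from 38.0 to 9.62, NREP, from 15.4 to 4.46, the lamin LMNA, from 6.09 to 1.89, the lincRNA AL033527.5, from 20.8 to 8.87, and NPLOC4, from 18.9 to 8.11. Of these 18 genes, 9 kept their call when any 1 library was left out, namely AC254633.1, DHRS3, CD38, CHI3L1, ACSL1, MYO1G, ARMH1, DDX56 and NCF1B. CTSL lost its call without ATRA replicate 2 (adjusted p = 0.0539) and AL033527.5 without any of the 9 libraries (highest adjusted p = 0.177). LGALS3, CAPN2, RCAN1, NREP, NDRG1, LMNA and NPLOC4 each lost it without at least 4 of the libraries. The count of 90 genes dropped to 41 without ATRA replicate 1, 48 without ATRA replicate 2, 59 without ATRA replicate 3, 58 without untreated replicate 1 and 49 without untreated replicate 2. Without untreated replicate 3 it was 63, with 48 of the 90 among them.

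Among the gene lists fixed before the data were examined, 3 of 20 passed the camera test for ATRA. Of 15 tested genes of lipid loading and LXR, the lipid-sensing nuclear receptor, 3 rose and none fell, and 8 rose when adjusted over the list alone (camera adjusted p = 2.03e-06, and 0.0309 with an estimated correlation). ACSL1 was joined there by PLIN2, the lipid droplet coat protein, which rose from 7.26 ± 3.18 to 38.5 ± 12.8 FPKM, and by PDK4, which rose from 0.549 ± 0.104 to 1.99 ± 0.0885 FPKM. Of 24 lysosome and protease genes, 2 rose and none fell, also when adjusted over the list alone (camera adjusted p = 1.35e-05, and 0.0309 with an estimated correlation). These were CTSL and CTSD, cathepsin D, which rose from 0.624 ± 0.168 to 4.63 ± 0.644 FPKM. Of 10 retinoid response genes, DHRS3 and CD38 rose and none fell, and 4 rose when adjusted over the list alone. The list passed the camera test (adjusted p = 0.00272) but not with an estimated correlation (adjusted p = 0.117), nor without untreated replicate 1 (adjusted p = 0.0548). PRAM1 was at 0.749 and 1.83 FPKM and TGM2 at 0.015 and 1.39 FPKM. Neither passed the test over all genes (adjusted p = 0.147 and 0.177).

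The other 17 lists did not pass for ATRA, with camera adjusted p between 0.107 and 0.999. Single members of them rose. MERTK, the macrophage receptor for dying cells, rose from 0.0714 ± 0.0236 to 3.77 ± 1.07 FPKM as 1 of 11 monocyte and macrophage surface markers, and 2 rose when adjusted over the list alone. NCF1, a subunit of the NADPH oxidase whose reads can be shared with its pseudogenes, rose from 0.934 ± 0.441 to 6.04 ± 1.49 FPKM as 1 of 5 genes of that list. IRF1 rose from 2.84 ± 0.869 to 9.93 ± 1.04 FPKM and PPARG, a lipid-sensing nuclear receptor, from 0.143 ± 0.00357 to 3.77 ± 2.26 FPKM, as 2 of 14 myeloid transcription factors. KIT, the stem cell factor receptor, fell from 3.12 ± 0.745 to 0.980 ± 0.219 FPKM as 1 of 11 genes of the MLL-fusion target and stem cell programme. NDRG1 was the 1 of 16 glycolysis and hypoxia genes that rose. Each of NCF1, IRF1, PPARG, KIT, PLIN2 and PDK4 lost its call without at least 2 of the 9 libraries, among them ATRA replicate 2 for all but PPARG (highest adjusted p = 0.0736, 0.0684, 0.101, 0.161, 0.0611 and 0.118). None passed in limma of 28 cell cycle, 22 MYC and ribosome biogenesis, 22 myeloid and general lncRNA, 19 adhesion and matrix, 15 cholesterol synthesis, 12 stress, 11 NF-kappaB, 11 p53 target, 11 interferon response, 7 AP-1, 7 cytokine or 3 granule genes. At an unadjusted p under 0.05 there were 3, 1, 3, 3, 0, 2, 3, 3, 3, 1, 1 and 1 members of these lists, in the same order. Median and mean log2 change had opposite signs for adhesion (-0.18 and 0.01), MYC (0.00 and -0.02) and myeloid transcription factors (-0.03 and 0.28), and the camera direction for cytokines was up although median and mean were -0.02 and -0.08. At the transcript level 53 transcripts rose and 18 fell of 15235. Of these 71, 32 were retained introns, as were 9187 of the 15235 tested.

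The second comparison asked what PMA changed. RGS1, a regulator of G protein signalling, rose from 0.0698 ± 0.0266 to 410 ± 56.5 FPKM (SD, n = 3 in each group), and FABP4, a fatty acid carrier of fat cells and macrophages, rose from 0.0505 ± 0.0506 to 97.4 ± 11.2 FPKM. The integrin ITGB5 rose from 0.260 ± 0.243 to 77.9 ± 11.2 FPKM and CTSL from 4.08 ± 2.56 to 206 ± 14.9 FPKM. CTSG, the neutrophil and monocyte granule protease cathepsin G, fell from 109 ± 45.0 to 0.0633 ± 0.110 FPKM, and the membrane protein MS4A6A fell from 74.0 ± 41.8 to 0.467 ± 0.329 FPKM. The lincRNA AC078850.1 rose from 0.00719 ± 0.0125 to 18.7 ± 0.422 FPKM, and the lincRNA LINC02169 fell from 153 ± 58.2 to 9.89 ± 2.72 FPKM. In limma, 781 genes rose and 1327 fell of 8500 (unadjusted p under 0.05 in 3171), among them 465 of the 1418 lncRNA genes, of which 139 rose, and 1585 of the 6913 protein-coding genes, of which 636 rose. A change of at least 2-fold was seen for 1631 of the 2108 genes. In 39.4% of all genes tested the 3 PMA values did not overlap the 3 untreated values, against 10% given by chance.

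The share of rising genes depended on the scaling between libraries, because the median log2 change of all genes was -0.20 in the values as deposited. Of the changed genes 37.0% rose as deposited, 52.3% (1019 up, 931 down) with median-of-ratios scaling and 49.0% (903 up, 941 down) with quantile normalization, and for lncRNA genes the share was 29.9%, 41.7% and 42.6%. The log2 changes, with the value relative to that median of all genes after each, were 9.48 and 9.69 for RGS1 (SE 0.209, adjusted p = 6.24e-09), 7.47 and 7.67 for FABP4 (adjusted p = 6.3e-08), 6.74 and 6.94 for ITGB5 (adjusted p = 5.69e-07) and 5.64 and 5.84 for CTSL (adjusted p = 5.36e-06). They were 5.24 and 5.44 for AC078850.1 (adjusted p = 2.11e-07), -7.53 and -7.33 for CTSG (adjusted p = 5.69e-07), -6.17 and -5.97 for MS4A6A (adjusted p = 1.55e-05) and -3.83 and -3.63 for LINC02169 (adjusted p = 4.11e-05). AC078850.1 (ENSG00000248187) lies on chromosome 4 at 128567972 to 128570531, and LINC02169 (ENSG00000259517) on chromosome 16 at 54245544 to 54270879, both on the minus strand of GRCh38. The other large rises were SPOCD1 (0.0493 and 75.8 FPKM), the kinase SGK1 (1.16 and 151), the actin-binding protein MTSS1 (0.186 and 44.1), the receptor HAVCR2 (0.114 and 31.8) and the lncRNA AC005280.3 (0.891 and 52.7), which shares exon bases with NUMB on the same strand. The other large falls were MYO1G (34.3 and 0.337 FPKM), the lncRNA CCDC26 (11.3 and 0.238), the thrombospondin THBS4 (11.2 and 0.204) and AL033527.5 (20.8 and 0.887). AC008894.2, antisense to RAB8A and HSH2D, AC092724.1 and the centromere protein CENPA were at 18.1, 11.5 and 10 FPKM in untreated cells and listed at 0 in all 3 PMA libraries. CENPA was also listed at 0 in ATRA replicate 1, against 14.13 and 11.96 FPKM in the other ATRA libraries, so a 0 for it can arise in a single library. These 20 genes kept their calls when any 1 library was left out, and without untreated replicate 3 there were 1803 changed genes, 1626 of them among the 2108.

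Of the 20 lists, 9 passed the camera test for PMA against untreated cells, 7 upward and 2 downward. Of 7 AP-1 and early response genes 6 rose and none fell, also when adjusted over the list alone (camera adjusted p = 2.03e-06, and 0.0380 with an estimated correlation). SPRED1, SPRY4 and DUSP6, inhibitors of the MAP kinase pathway, rose from 0.370 ± 0.314 to 20.6 ± 3.05, from 0.00952 ± 0.00443 to 1.44 ± 0.142 and from 0.248 ± 0.2 to 3.90 ± 0.196 FPKM. Only 15 of the 26 members of this list were in the table. The 3 named here are not AP-1 factors, so a rise of the AP-1 factors as a group is not shown. Of 7 inflammatory cytokine and chemokine genes 5 rose and none fell, with 5 and 1 when adjusted over the list alone (camera adjusted p = 3.24e-05, and 0.0309 with an estimated correlation). IL1B rose from 0.126 ± 0.0309 to 21.4 ± 3.18 FPKM and CCL20 from 0.0874 ± 0.151 to 15.3 ± 2.67 FPKM. Of the 30 members of this list 21 were in the table, and 7 passed the filter on low values. IL1B, CCL3 and, in the AP-1 list, SPRY4 were below 0.5 FPKM in every untreated and ATRA library and passed the filter through PMA. The filter let in members that rose from near 0 but not those that stayed there. This tilts the counts and tests of both lists upward. Of 15 lipid loading and LXR genes 9 rose and 2 fell, also when adjusted over the list alone (camera adjusted p = 4.54e-06, and 0.0334 with an estimated correlation). PLIN2 rose from 7.26 ± 3.18 to 234 ± 16.6 FPKM and the scavenger receptor CD36 from 1.28 ± 0.540 to 21.5 ± 11.1 FPKM. Of 19 adhesion and matrix genes 9 rose and 1 fell, with 11 and 1 when adjusted over the list alone (camera adjusted p = 7.32e-06, and 0.0309 with an estimated correlation). ICAM1 rose from 0.126 ± 0.0519 to 3.69 ± 1.46 FPKM, and the integrin ITGA4 fell from 7.43 ± 0.714 to 1.96 ± 0.45 FPKM. Of 24 lysosome and protease genes 9 rose and none fell, also when adjusted over the list alone (camera adjusted p = 1.31e-05, and 0.0309 with an estimated correlation), among them the membrane protease MMP14, from 0.969 ± 0.216 to 6.38 ± 1.27 FPKM.

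The other 4 lists that passed lost that call with an estimated correlation. For NF-kappaB and granule genes the estimate was -0.0179 and -0.154, below the preset 0.01, so a higher correlation among members was not the reason there. Of 28 cell cycle genes 16 fell and none rose, and 21 fell when adjusted over the list alone (camera adjusted p = 3.33e-06, and adjusted p = 0.105 with an estimated correlation). With median-of-ratios scaling 14 fell and with quantile normalization 9. The kinetochore kinase BUB1 fell from 26.1 ± 8.24 to 3.94 ± 0.844 FPKM, the topoisomerase TOP2A from 3.14 ± 1.21 to 0.45 ± 0.267 FPKM, and the DNA helicase subunit MCM5 from 6.42 ± 0.772 to 2.62 ± 0.192 FPKM. Of 11 monocyte and macrophage surface markers 7 rose and 2 fell, with 7 and 3 when adjusted over the list alone (camera adjusted p = 0.00242, and adjusted p = 0.0938 with an estimated correlation). CSF1R, the receptor of macrophage colony-stimulating factor, rose from 2.27 ± 0.379 to 10.1 ± 0.755 FPKM and ITGAX from 7.27 ± 3.52 to 41 ± 7.17 FPKM. Of 11 NF-kappaB pathway genes 4 rose and none fell, also when adjusted over the list alone (camera adjusted p = 0.00934, and adjusted p = 0.0938 with an estimated correlation), among them TNFAIP3, from 0.985 ± 0.222 to 5.72 ± 1.01 FPKM, and NFKBIA, from 3.49 ± 0.386 to 14.6 ± 3.03 FPKM. Of 3 granule genes CTSG and the receptor CSF3R fell, the latter from 33.5 ± 7.84 to 2.35 ± 0.587 FPKM (camera adjusted p = 0.00934, and adjusted p = 0.0938 with an estimated correlation). The list medians relative to the median of all genes were 3.34 for cytokines, 2.62 for lipid loading, 2.39 for AP-1, 1.51 for macrophage markers, 1.42 for adhesion, 0.87 for lysosome and 0.62 for NF-kappaB genes. They were -0.95 for cell cycle and -3.37 for granule genes. LYZ was at 584 ± 522 and 146 ± 13.5 FPKM and did not pass.

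For the 11 lists that did not pass for PMA, camera adjusted p lay between 0.0593 and 0.976. Members of them moved both ways. Among 14 myeloid transcription factors 5 rose, KLF4 from 2.54 ± 1.37 to 11.8 ± 2.0 FPKM, and 5 fell, IRF8 from 7.57 ± 1.43 to 0.530 ± 0.246 and GFI1 from 6.48 ± 1.62 to 1.08 ± 0.0725 FPKM. Of 11 genes of the MLL-fusion target and stem cell programme 6 fell and 1 rose, with KIT from 3.12 ± 0.745 to 0.203 ± 0.0893 FPKM and HOXA9, whose transcript holds MIR196B, from 1.98 ± 0.781 to 0.325 ± 0.249 FPKM. Of 11 p53 targets and cycle inhibitors 3 rose and 2 fell, with CDKN1A, the cyclin-dependent kinase inhibitor p21, from 0.594 ± 0.378 to 32.6 ± 23.9, PLK3 from 0.946 ± 0.386 to 17.5 ± 3.94 and MDM2 from 4.03 ± 0.579 to 1.31 ± 0.436 FPKM. Of 10 retinoid response genes 4 rose and 3 fell, with DHRS3 rising to 6.01 ± 0.592 FPKM and CD38 falling to 0.101 ± 0.0511 FPKM. Of 22 lncRNAs with known roles 7 rose and 4 fell, with LUCAT1 from 0.0148 ± 0.0256 to 11.9 ± 4.78 and CYTOR from 26.2 ± 5.06 to 83.4 ± 27.4 FPKM, while LINC01010 was listed at 0 in all untreated libraries and at 2.06 ± 0.605 FPKM with PMA. Glycolysis and hypoxia had 3 of 16 up and 1 down, interferon response 1 of 11 up and 3 down, cholesterol synthesis 1 of 15 up and 3 down (3 and 2 with median-of-ratios scaling, 2 and 2 with quantile normalization), stress 2 of 12 up and 1 down, and NADPH oxidase none of 5 in limma, with 2 at an unadjusted p under 0.05. In NADPH oxidase 1 gene rose with either of these scalings, and 1 fell with scaling to the same sum. The interferon genes that rose were 2 with either scaling, the lncRNAs that fell 2 with median-of-ratios scaling, the p53 targets that fell 1 with either and the stress genes that rose 3 and 1. In MYC and ribosome biogenesis ODC1 and POLR1B fell of 22 genes, but none passed when adjusted over the list alone, both calls were lost without PMA replicate 1, and 1 gene fell with either scaling. In the glycolysis list PKM rose from 23.8 ± 1.69 to 55.7 ± 4.21 FPKM and the glucose transporter SLC2A1 fell from 2.47 ± 0.939 to 0.512 ± 0.254 FPKM. The stress list held HMOX1, which rose from 0.201 ± 0.156 to 4.20 ± 0.948 FPKM. The median was negative and the mean positive for p53 targets (-0.38 and 0.60), retinoid response (-0.32 and 0.47), the lncRNA list (-0.10 and 0.33), stress (-0.14 and 0.08) and NADPH oxidase (-0.01 and 0.05). The reverse held for myeloid transcription factors (0.04 and -0.03). Median and mean were -0.07 and -0.25 for MYC and ribosome biogenesis while camera pointed up. The medians of that list, cholesterol synthesis, NADPH oxidase, the lncRNA list and stress changed sign with the scaling between libraries.

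A few lists had fewer than 3 tested members and no set test. Of 2 tested B cell markers CD22 rose with PMA from 0.00331 ± 0.00573 to 9.53 ± 0.543 FPKM (log2 change 4.32, adjusted p = 5.69e-07) and CD79B fell from 1.80 ± 0.383 to 0.0701 ± 0.0715 FPKM (log2 change -2.0, adjusted p = 2.29e-04). Neither passed with ATRA. The platelet marker TREML1 rose with PMA from 0.213 ± 0.137 to 2.61 ± 0.291 FPKM (adjusted p = 4.42e-04). It was at 1.29 ± 0.539 FPKM with ATRA (adjusted p = 0.0671). The MHC class II genes CD74 and CIITA and the retinal gene ROM1 passed in none of the 3 comparisons in limma (adjusted p between 0.0834 and 0.975). No marker of T and NK cells, erythroid cells or epithelium and fibroblasts passed the filter on low values, and no mitochondrially encoded gene was in the table.

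**Figure D1:**
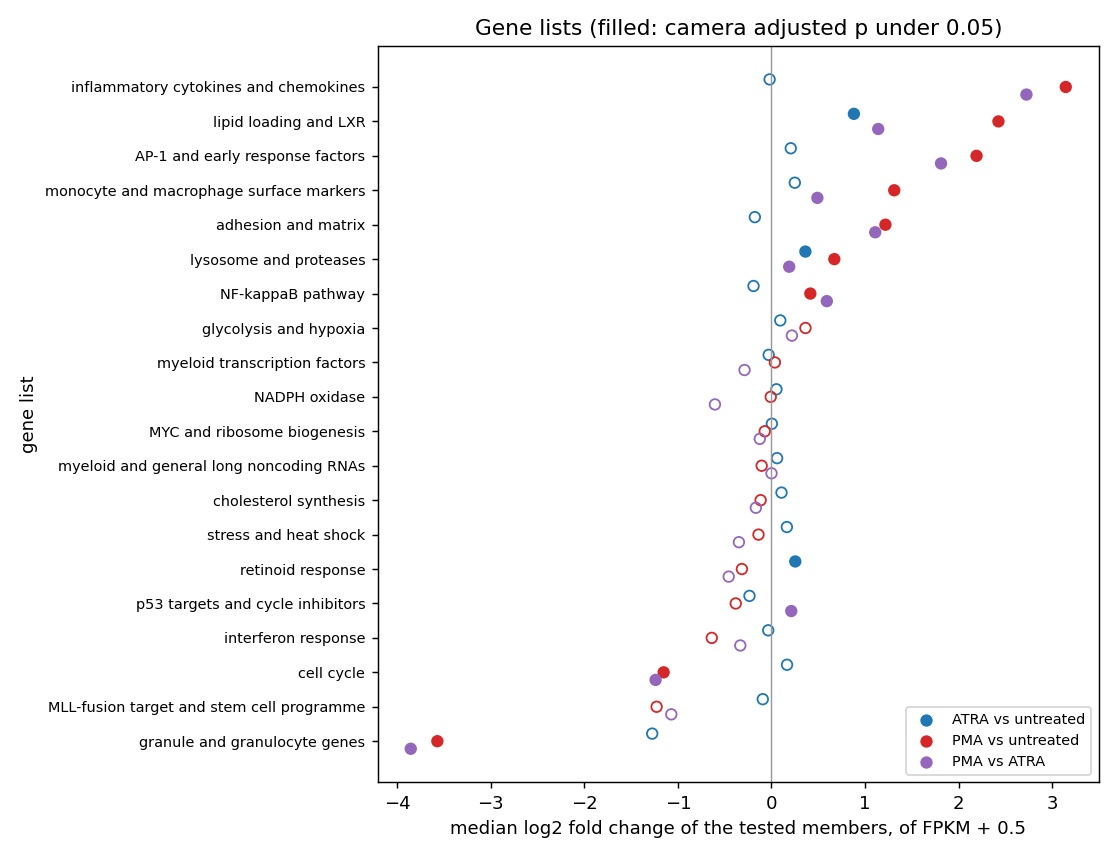
Median log2 change of the tested members of each of the 20 gene lists (horizontal axis, log2 of FPKM plus 0.5) for ATRA against untreated, PMA against untreated and PMA against ATRA, with filled points where camera gave an adjusted p under 0.05. The cytokine list, the lipid list and the list of AP-1 and early response genes lay highest for PMA against untreated. The granule and cell cycle lists were the filled points below 0.

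The third comparison tested the difference between the inducers, whose doses are of different compounds and not matched. CD38 was at 21.6 ± 0.639 FPKM with ATRA and 0.101 ± 0.0511 FPKM with PMA, and MS4A6A at 119 ± 62.3 and 0.467 ± 0.329 FPKM. RGS1 was at 0.228 ± 0.0905 FPKM with ATRA and 410 ± 56.5 FPKM with PMA, and the intermediate filament protein VIM at 0.494 ± 0.229 and 38.4 ± 16.1 FPKM (SD, n = 3 in each group). CSF3R, the receptor of granulocyte colony-stimulating factor, was at 40.4 ± 5.10 and 2.35 ± 0.587 FPKM, and RASGRP2, an activator of Rap1, at 28.6 ± 3.10 and 1.53 ± 0.319 FPKM. In limma 668 genes were higher and 1105 lower with PMA, and an unadjusted p under 0.05 was seen for 2920. Of 1418 lncRNA genes 110 were higher and 266 lower. The 3 PMA and 3 ATRA values did not overlap in 41.4% of genes, against 10% given by chance. The median log2 change of all genes was -0.21, and the share of higher genes was 37.7% as deposited, 53.3% (875 up, 766 down) with median-of-ratios scaling and 49.5% (787 up, 803 down) with quantile normalization. For lncRNA genes that share was 29.3%, 42.5% and 41.6%.

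The log2 changes, with the value relative to the median of all genes after each, were 9.14 and 9.35 for RGS1 (adjusted p = 9.03e-09), 5.24 and 5.45 for VIM (adjusted p = 9.1e-06), -6.88 and -6.67 for MS4A6A (adjusted p = 9.1e-06) and -5.20 and -4.99 for CD38 (adjusted p = 3.39e-07). They were -3.85 and -3.64 for CSF3R (adjusted p = 7.89e-06). The osteopontin gene SPP1 was also higher with PMA (adjusted p = 0.00495), but its 3 PMA values were 21.3, 26.9 and 790 FPKM. The other genes with the largest rises were SPOCD1, ITGB5, FABP4, SGK1, MTSS1, AC005280.3 and AC078850.1, which also rose against untreated cells. The other large falls were CTSG (43.1 and 0.0633 FPKM), CNTN4 (17.9 and 0.567), THBS4 (10.3 and 0.204) and EMB (252 and 24.8), with AC008894.2 and AC092724.1 at 14.6 and 11.6 FPKM with ATRA and listed at 0 with PMA. These 20 genes kept their calls when any 1 library was left out, and without untreated replicate 3 there were 2012 changed genes, 1734 of them among the 1773.

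Of the lists, 10 passed for PMA against ATRA, and 3 of these also with an estimated correlation. These 3 were AP-1 and early response (6 of 7 up, camera adjusted p = 2.03e-06, and 0.0380 with an estimated correlation), cytokines and chemokines (5 of 7 up, 7.32e-06 and 0.0309) and adhesion and matrix (8 of 19 up and 1 down, 10 and 1 when adjusted over the list alone, 7.32e-06 and 0.0309). In these lists IL1B was at 0.154 ± 0.0979 FPKM with ATRA and 21.4 ± 3.18 with PMA, DUSP2 at 0.489 ± 0.391 and 5.0 ± 1.73, and the integrin ITGA5 at 4.18 ± 0.712 and 15.4 ± 2.24 FPKM. The AP-1 and cytokine lists are tilted upward here too, since IL1B, CCL3 and SPRY4 passed the filter on low values through PMA. Of 28 cell cycle genes 17 were lower with PMA, and 24 when adjusted over the list alone (camera adjusted p = 2.03e-06, and adjusted p = 0.0938 with an estimated correlation), with the cyclin CCNB1 at 5.47 ± 1.76 and 0.454 ± 0.229 FPKM and TOP2A at 5.23 ± 0.644 and 0.45 ± 0.267 FPKM. NF-kappaB genes had 3 of 11 up (camera adjusted p = 0.00196, and adjusted p = 0.0552 with an estimated correlation), with NFKBIA at 2.77 ± 0.577 and 14.6 ± 3.03 FPKM. Lipid loading and LXR genes had 7 of 15 up and 4 down (camera adjusted p = 0.00304, and adjusted p = 0.0979 with an estimated correlation), with FABP5 at 0.545 ± 0.198 and 11.6 ± 2.70 FPKM and the nuclear receptor NR1H2 at 11.4 ± 0.340 and 1.74 ± 0.652 FPKM. Macrophage markers had 5 of 11 up and 2 down (camera adjusted p = 0.0341, and adjusted p = 0.185 with an estimated correlation), with TLR2 at 3.35 ± 0.317 and 12.4 ± 4.12 FPKM. Granule genes had 2 of 3 down (camera adjusted p = 0.0341, and adjusted p = 0.129 with an estimated correlation), p53 targets 4 of 11 up and 1 down (camera adjusted p = 0.0357, and adjusted p = 0.125 with an estimated correlation) and lysosome genes 3 of 24 up (camera adjusted p = 0.0447, and adjusted p = 0.140 with an estimated correlation). With median-of-ratios scaling 6 lysosome genes were higher, and with quantile normalization 4. The last 4 calls also depended on single libraries. Without ATRA replicate 3 adjusted p was 0.0577 for granule genes, 0.0727 for p53 targets and 0.0727 for lysosome and proteases. Without ATRA replicate 1 it was 0.0529 for macrophage markers and 0.0718 for lysosome and proteases. For list lysosome and proteases, PMA vs ATRA, it was 0.0552 without untreated replicate 1 and 0.0513 without untreated replicate 3. Relative to the median of all genes, the list medians were 2.02 for AP-1, 2.94 for cytokines, 1.32 for adhesion, 1.35 for lipid loading, -1.02 for cell cycle and -3.64 for granule genes.

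The 10 lists that did not pass here had camera adjusted p between 0.107 and 0.969. Among them IRF1 was at 9.93 ± 1.04 FPKM with ATRA and 2.23 ± 0.430 with PMA (3 of 14 myeloid transcription factors higher, 4 lower), NDRG1 at 32.1 ± 9.07 and 5.33 ± 2.93 (2 of 16 glycolysis genes higher, 1 lower) and DDIT4 at 10.7 ± 2.21 and 1.85 ± 0.369 FPKM (1 of 12 stress genes higher, 2 lower). The kinase CDK6 was at 2.72 ± 0.411 and 6.27 ± 0.374 FPKM (1 of 11 genes of the MLL-fusion target and stem cell programme higher, 6 lower). Of 15 cholesterol synthesis genes 1 was higher and 4 were lower. The antiviral gene RSAD2 was at 2.71 ± 0.683 and 0.329 ± 0.172 FPKM (1 of 11 interferon response genes higher, 1 lower) and the retinoic acid receptor gene RARG at 0.00919 ± 0.0159 and 3.03 ± 0.629 FPKM (2 of 10 retinoid response genes higher, 4 lower). Of the lncRNA list 6 of 22 were higher and 4 lower, and of MYC and ribosome biogenesis 1 of 22 was lower, ODC1, listed at 0 with PMA. Of 5 NADPH oxidase genes 2 were lower as deposited, but 1 was higher and none lower with median-of-ratios scaling or quantile normalization. The stress genes that were higher were 2 with either scaling. For MYC and ribosome biogenesis camera pointed up while median and mean were -0.12 and -0.23, and the medians of that list and of cholesterol synthesis changed sign with the scaling.

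The study was made to find RNAs that change with both inducers. AC254633.1 rose with both, to 9.18 ± 1.21 FPKM with ATRA and 12.4 ± 1.23 with PMA, and so did its neighbour DHRS3, to 10.5 ± 1.34 and 6.01 ± 0.592 FPKM. AC068580.1 rose from 0.951 ± 0.138 to 5.91 ± 0.937 and 3.58 ± 0.530 FPKM and AC068580.3 from 0.180 ± 0.147 to 1.49 ± 0.154 and 1.04 ± 0.130 FPKM, both within CTSD, which also rose with both. AC091563.1 fell from 7.15 ± 2.40 to 0.770 ± 0.295 and 0.184 ± 0.147 FPKM and LINC00211 from 5.39 ± 1.39 to 0.625 ± 0.396 and 0.210 ± 0.0813 FPKM. In limma 52 genes changed the same way with both inducers, 29 upward and 23 downward, and 10 in opposite directions, while 28 passed for ATRA alone. Among lncRNA genes 15 changed the same way, 6 upward and 9 downward, and 3 in opposite directions.

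Lists of these sizes drawn independently would share 5.24 rising and 5.15 falling genes, and 1.47 and 2.53 lncRNA genes. Unchanged groups simulated with a shared untreated group shared 0.01 genes on average and at most 1 in 100 draws. Such groups give almost no calls in either comparison, so a count near 0 was fixed in advance. It does not measure what the shared controls add when PMA changes many genes. Across genes the log2 changes of both inducers had a correlation of 0.364, against 0.498 in the simulation, and a covariance of 0.2069 against 0.0868, a difference of 0.1201. For lncRNA genes the correlation was 0.397 against 0.498, and the covariance 0.2467 against 0.0751, a difference of 0.1716. Both changes had the same sign in 63.2% of all genes and 62.8% of lncRNA genes, against 66.7% of all genes in the simulation. Of these measures only the covariance lay above the simulation. Genes are not independent replicates, and the 3 untreated libraries could not be divided between the comparisons. Part of the overlap beyond independent draws may therefore come from the shared controls. The count of 52 was 26 without ATRA replicate 1, 27 without untreated replicate 2, 29 without ATRA replicate 2, 32 without PMA replicate 2 and 41, with 30 of the 52 among them, without untreated replicate 3. The count of 15 lncRNA genes was 6 without ATRA replicate 1, 8 without untreated replicate 2 and 9 without PMA replicate 2 or PMA replicate 3.

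The 5 lncRNAs with the largest rises in both were AC254633.1, AL157813.1, AC068580.1, AL020997.2 and AC068580.3. On GRCh38 AL157813.1 lies on chromosome 13 at 48532013 to 48532599, in an intron of RCBTB2 on the same strand, and AL020997.2 on chromosome 1 at 27773858 to 27774041, in an intron of STX12. AC068580.1 lies on chromosome 11 at 1763009 to 1763749, in an intron of CTSD on the same strand, and AC068580.3 at 1760348 to 1762486, where it shares 493 exon bases with CTSD on the opposite strand. AL157813.1 rose from 0.507 ± 0.474 to 3.17 ± 0.205 FPKM with ATRA and 2.81 ± 0.367 with PMA, and AL020997.2 from 0.633 ± 0.109 to 2.09 ± 0.254 and 2.20 ± 0.394 FPKM. The 5 with the largest falls were AC091563.1 (chromosome 8, 120052180 to 120056201, 1267 bases from DEPTOR), LINC00211 (chromosome 2, 37820498 to 37876274), AC104211.2 (chromosome 8, 92668660 to 92683450), KDM4A-AS1 (chromosome 1, 43685123 to 43708138) and DLGAP1-AS3 (chromosome 18, 3878058 to 3897069). KDM4A-AS1, which shares 464 exon bases with KDM4A, fell from 5.46 ± 0.456 to 1.02 ± 0.473 and 0.907 ± 0.294 FPKM, AC104211.2 from 2.92 ± 1.43 to 0.140 ± 0.109 and 0.0490 ± 0.0557 FPKM, and DLGAP1-AS3 from 1.64 ± 0.264 to 0.247 ± 0.0926 and 0.00455 ± 0.00789 FPKM. For these 10 the adjusted p was between 4.21e-05 and 0.0325 with ATRA and between 1.02e-06 and 0.00419 with PMA. Strand use in the counting was not stated, so the values of antisense, intronic and overlapping genes are uncertain. The ATRA call was lost without 8 of the 9 libraries for AL020997.2 (highest adjusted p = 0.136), without 5 for AL157813.1 (0.0643), without ATRA replicate 1 or 2 for AC068580.3 (0.0546), and without untreated replicate 2 or ATRA replicate 1 for AC104211.2 (0.0543).

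Of the 10 genes that moved in opposite directions, 7 rose with ATRA and fell with PMA: CD38, the fructose transporter SLC2A5, the receptor IL31RA, NDFIP1, C5orf56, EIF1B-AS1 and AC020658.2. IL31RA and AC020658.2 were at only 0.488 and 0.315 FPKM untreated and at 0.00413 and 0.0232 FPKM with PMA. Their falls thus lie near the floor, and they passed the filter of 0.5 FPKM through their ATRA values of 2.47 and 1.95. C5orf56 was at 5.50 FPKM untreated, 18.8 with ATRA and 1.15 with PMA, and SLC2A5 at 2.12, 10.4 and 0.684 FPKM, and these 2 were picked for mention after the values had been seen. LGALS3, ARHGAP10 and the DNA repair gene XRCC1 fell with ATRA and rose with PMA, LGALS3 from 3.42 to 0.513 and 11.1 FPKM.

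**Figure D2:**
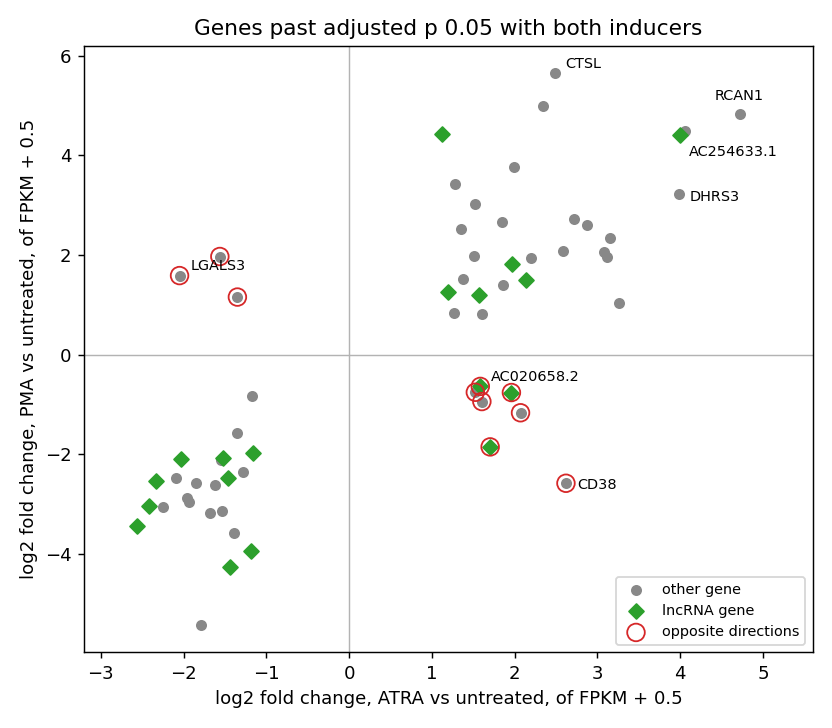
Log2 change with ATRA (horizontal axis) and with PMA (vertical axis), each against untreated cells and of FPKM plus 0.5, for the 62 genes that passed in both comparisons, with lncRNA genes as green diamonds. Of these genes 52 lie in the quadrants where both changes have the same sign, and the 10 circled ones have opposite signs.

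AC098613.1, ADAP1 and NRDC (NRD1), which the study's title names, were chosen by the study and are not independent evidence. AC098613.1 (ENSG00000223552) was below the filter on low values. Its FPKM was listed at 0 in all 3 untreated libraries, at 0.502, 0.501 and 0.667 with ATRA and at 0.123, 0.162 and 0.0659 with PMA, which correspond to about 9.2, 10.6 and 12.6 and about 2.3, 2.9 and 1.1 fragments at the estimated depths. In the limma fit of 21172 genes without the filter the change with ATRA passed (adjusted p = 0.0111), that with PMA did not (adjusted p = 0.179), and PMA was lower than ATRA by a log2 change of -0.78 (adjusted p = 0.0061). The means were 0.557 FPKM with ATRA and 0.117 with PMA. The 0.5 added before the log is above every PMA value and close to the ATRA values, so these log2 changes understate the ratios of FPKM. The missing call with PMA therefore does not show that the gene stayed unchanged. ADAP1 was at 19.6 ± 4.51 FPKM untreated and 24.6 ± 4.81 with ATRA (log2 change 0.33, SE 0.259, adjusted p = 0.636), and fell to 6.95 ± 1.01 with PMA (log2 change -1.42, or -1.21 relative to the median of all genes, adjusted p = 0.00338). NRDC was at 31.2 ± 17.8 FPKM untreated and 16.7 ± 1.46 with ATRA (log2 change -0.75, SE 0.354, adjusted p = 0.412). Its untreated values were 22.2, 19.64 and 51.75 FPKM, and without untreated replicate 3 the change with ATRA was -0.32. NRDC fell to 9.81 ± 2.29 with PMA (log2 change -1.50, adjusted p = 0.0123). Adjusted over the list alone, 2 of these 2 tested genes passed with PMA and none with ATRA. PMA differed from ATRA for ADAP1 (log2 change -1.74, adjusted p = 0.00107), but NRDC did not pass (log2 change -0.76, adjusted p = 0.164), except without untreated replicate 3 (adjusted p = 0.0318).

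**Figure D3:**
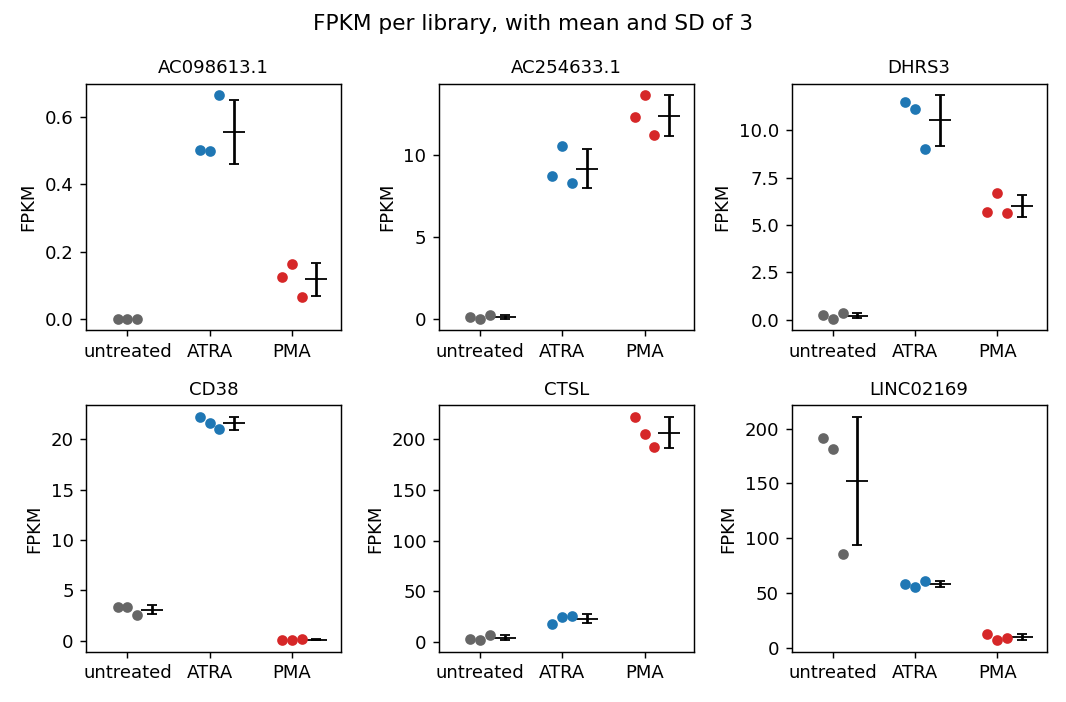
FPKM of 6 genes in each of the 3 untreated, 3 ATRA and 3 PMA libraries (points), with the mean and SD of each group beside them unless it is listed at 0 in all 3. CD38 was highest with ATRA and lowest with PMA, CTSL and AC254633.1 were higher with both inducers, and LINC02169 was lowest with PMA.

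At the transcript level 924 transcripts rose and 1237 fell with PMA of the 15235 tested, and 753 were higher and 1056 lower with PMA than with ATRA. Transcripts of 1 gene moving in opposite directions were found in 10 genes for PMA against untreated, 8 for PMA against ATRA and none for ATRA against untreated in limma, where 28 genes had such a pair at an unadjusted p under 0.05. In P4HB, which encodes protein disulfide isomerase, the retained-intron transcript P4HB-210 rose from 0.336 ± 0.1 to 55.7 ± 38.8 FPKM with PMA (log2 change 5.84) while P4HB-215 fell from 1.43 ± 0.352 to 0.313 ± 0.250 FPKM (log2 change -1.29). In the transporter gene SLC12A8 the log2 changes were 2.85 and -1.61, in RANBP17 1.48 and -1.46, in CCDC57 2.30 and -1.25 and in TAF1D 1.20 and -1.10. The division of reads among isoforms is an estimate, and the count of 10 genes was between 4 and 6 whenever 1 library was left out, whichever of the 9 it was. The count of 8 for PMA against ATRA also went down or up with the library left out.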

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

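Leaving out transcripts with a small RNA gene, and the alternatives for isoform switches, for counts of changed lncRNA genes and for the share of rising genes, were chosen after the data had been seen, and the other alternatives before. Of the named-gene values under the alternatives, 5715 kept direction and call, 191 lost the call, 44 gained it and 16 changed sign, and of the list values 1107, 29, 16 and 39. All 55 that changed sign were uncalled before and after. Leaving out 1 library in turn gave 41 to 75 changed genes for ATRA, 26 to 41 genes and 6 to 12 lncRNA genes shared by both inducers, 33 to 63 transcripts for ATRA, 1414 to 1894 for PMA and 1160 to 1996 for PMA vs ATRA, and 4 to 6 isoform switches for PMA and 3 to 11 for PMA vs ATRA. With a mean FPKM of at least 2 there were 1140 changed genes for PMA and 985 for PMA vs ATRA, 36, 828 and 744 transcripts for ATRA, PMA and PMA vs ATRA, 9 shared lncRNA genes, and 2 and 4 isoform switches for PMA and PMA vs ATRA. Without the filter on low values there were 32 shared lncRNA genes and 4 isoform switches for PMA vs ATRA. With only the 2 groups compared there were 45 genes and 29 transcripts for ATRA. With an estimated correlation, in the fit of all 9 libraries, 10 of 22 list calls stayed.

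No sign was seen that the replicate numbers pair the libraries, which does not establish that they were unpaired. Deviations of same-numbered libraries had correlations of -0.049 to 0.027, the others -0.046 to 0.058, and 2 of 9 libraries matched their own number best. With the replicate block there were 57 changed genes and 23 transcripts for ATRA, 34 shared genes, and 4 and 5 isoform switches for PMA and PMA vs ATRA, and the median of cholesterol synthesis for PMA was -0.116 while its camera direction changed.

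The uncalled results that changed direction were these, with list values as medians where the direction is that of camera. CD74 for PMA vs ATRA was 0.037 scaled to the same sum, 0.18 with median-of-ratios scaling and 0.143 with quantile normalization. Adhesion for ATRA was -0.292 with a pseudocount of 0.1 and -0.158 with quantile normalization, and cholesterol synthesis for PMA was 0.114 with median-of-ratios scaling. With a mean of at least 2 FPKM cytokines were at -0.137 and p53 targets at 0.262 for ATRA, and myeloid transcription factors at -0.605 and MYC at -0.072 for PMA. Without the filter interferon response was at 0.122, 0.095 and -0.008 for ATRA, PMA and PMA vs ATRA and MYC at -0.072 for PMA. NOP56 for ATRA was at 0.094 without transcripts holding a small RNA gene. Over the libraries left out, values for ATRA ranged from -0.839 to 0.204 for CD74, -0.235 to 0.01 for CD79B, -0.043 to 0.937 for CIITA, -0.076 to 0.053 for NCF4, -0.137 to 0.691 for ROM1, -0.279 to 0.014 for adhesion, -0.03 to 0.063 for cytokines, -0.073 to 0.173 for interferon response, -0.079 to 0.111 for MYC and -0.139 to 0.106 for myeloid transcription factors. For PMA they ranged from -0.867 to 0.176 for CD74, -0.11 to 0.474 for RAC2, -0.359 to -0.014 for cholesterol synthesis, -0.793 to -0.348 for interferon response and -0.158 to 0.009 for MYC. For PMA vs ATRA they ranged from -0.15 to 0.073 for CD74, -0.482 to 4.135 for LYZ, -0.232 to 0.825 for ROM1, -0.424 to -0.203 for interferon response and -0.506 to -0.188 for stress.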

Other observations

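The tests of chance splits, of untreated replicate 3 and of scaling between libraries were chosen after the results had been seen, and the others before. LNCAROD (ENSG00000231131), a lincRNA picked here after its values were seen, was at 0.0621 ± 0.0581 FPKM in untreated cells, 0.715 ± 0.0196 with ATRA and 11.6 ± 1.49 with PMA (SD, n = 3). It rose with both inducers in limma, with log2 changes of 1.12 (adjusted p = 0.0366) and 4.42 (adjusted p = 5.69e-07). Of 166 pseudogenes tested 51 fell and 5 rose with PMA, among them PDCD6IPP2, which fell from 19.95 ± 7.74 to 3.24 ± 1.07 FPKM. As a class they passed camera downward (adjusted p = 0.0128, and adjusted p = 0.106 with an estimated correlation), and their reads can be shared with the parent genes.

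Under PMA lncRNA genes moved with the gene beside them, and the correlations with ATRA were 0.246 without overlap and 0.334 with it. Across 283 pairs within 10 kb without overlap the correlation of log2 changes was 0.36 (95% interval 0.215 to 0.479, permutation p = 1e-05, the smallest the permutations can give), so regulation shared along the locus may be part of it. Reads of an overlapping gene counted in the lncRNA cannot be told apart from it in the 593 overlapping pairs, whose correlation of 0.407 exceeded the other by 0.0468 (interval -0.103 to 0.208). The correlation was 0.617 in 235 pairs on the same strand and 0.297 in 345 on opposite strands. Both inducers were measured against the same untreated libraries, so noise along a locus in these enters every one of these correlations and was not tested apart, and genes are not independent replicates.

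Also under PMA, lncRNA genes lay lower than protein-coding genes, with a difference of -0.201 in median log2 change. A low level of lncRNA genes was argued against, since the difference was -0.198 (interval -0.253 to -0.124) after matching on mean FPKM. That interval was drawn over genes, which are not independent replicates. The difference within each library moved by -0.173, from 0.062 ± 0.022 in untreated to -0.111 ± 0.005 in PMA libraries, which restates the pattern. A single scaling factor per library moves genes of the same level alike, so the difference after matching argues against such a factor. With quantile normalization 42.6% of the changed lncRNA genes rose, against 49.0% of all changed genes. Other kinds of scaling between libraries stay open. The class did not pass camera (adjusted p = 0.107), so a lower output of lncRNA genes under PMA may be named as a hypothesis only.

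Untreated replicate 3 stood apart from the other untreated libraries, and no biological explanation was tested. PMA replicate 3 had a similar estimated depth, 25.1 M against 25.4 M, and a within-group correlation of 0.892. This argued against lower depth only as far as the estimates hold, and so small a gap does not rank the 2 libraries. Untreated replicate 3 had a mean correlation of 0.804 with ATRA and 0.640 with PMA libraries, against 0.840 with its own group. This argued against a swap with PMA. Untreated replicate 1 lay nearer to ATRA, at 0.872, than to its own group, at 0.866, but that mean includes untreated replicate 3. With untreated replicate 2 alone it had 0.891. By pairs, untreated replicate 3 had 0.842 and 0.839 with the other untreated libraries, against 0.799 to 0.814 with ATRA libraries. The ATRA libraries had 0.891 to 0.897 with each other and at most 0.878 with an untreated library. These values argued against a swap with ATRA as well. A sample from outside the series stays open. More intron-derived RNA also stays open. Retained-intron and sense-intronic transcripts were each compared with processed transcripts, and the larger of the 2 median differences was 0.103. Most of the sense-intronic excess of untreated replicate 3 came from AC006064.5, which holds SCARNA10 and was at 1122 FPKM against 253.6 and 321.4. Without that transcript the share was still 0.99% against 0.84% and 0.87%.

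In 1079 genes with both kinds of isoform, retained-intron transcripts lay below processed transcripts of the same gene under PMA by a median of -0.077 (interval -0.109 to -0.027, sign-flip permutation p = 0.0022), against -0.01 with ATRA (sign-flip permutation p = 0.64). The interval and the sign flips treat genes as units. Genes are not independent replicates, so neither measures the spread between libraries. A shift in intron retention under PMA could explain it but stays open, since protein-coding isoforms were not analysed here and the division of reads among isoforms is an estimate.

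The splits of the libraries into 3 and 3 are too few, at 10 with the real one included, for a share under 0.05. The real split gave 90, 2108 and 1773 genes for ATRA, PMA and PMA vs ATRA and the highest other 2, 2 and 2, and for transcripts it gave 71, 2161 and 1809 and the highest other 5, 2 and 3. In each of these the real split alone, 1 of the 10, reached its count. For genes changed the same way by both inducers, 3 of 100 splits of the 9 libraries, the real one included, gave 52 or more, and the highest other gave 1329. For lncRNA genes changed the same way 3 of 100 gave 15 or more, and the highest other gave 292. These splits do not decide whether chance gave the overlap, because 95 of the 99 others divided the PMA libraries, which all but fixes a count near 0, and 84 of these gave no gene. The other 2 splits that reached the real counts each placed the 3 PMA libraries together as the untreated group. That puts the PMA difference into both comparisons, so their large counts follow from the placing. A further 2 splits kept the PMA libraries together as the PMA group and gave 1 and 0 genes, which are too few splits to decide.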
